A study of Sus scrofa with 16 samples.

How the data were processed

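RNA was extracted from liver and subcutaneous backfat with a RiboPure kit and biotin-labelled cRNA was hybridised to Affymetrix porcine arrays, per the labels' protocols. The values the authors deposited are log2 expression values made with GCRMA, which corrects background by probe sequence, normalizes arrays by quantiles and summarises probes to probe sets. GCRMA is named in the submitters' processing notes with no version. Its settings, and whether all 16 arrays were normalized together, are not given in the sources used here. GCRMA leaves unexpressed probe sets near a low floor, so that differences against that floor depend on the background model. No scan date or batch is given, so a batch could not be tested.

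The table held 24123 probe sets, of which 124 controls were left out of every test. Probe sets were named from the platform annotation. It gave 1 gene symbol to 10099 probe sets and several to 198, and did not list 13826, which stay unnamed. Of the 10099, 9989 matched a gene of the RefSeq table of the current pig reference assembly by Entrez ID, and 0 symbols changed. No gene was named from a probe set with several symbols. No column of values was left unused, and no 2 arrays held identical values.

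Groups came from tissue, sex and feeding level in the labels. Each of the 8 groups had 2 arrays, and each sex or feeding level within a tissue 4. A probe set entered a test when it was above 4 (log2) on at least 2 arrays of the fit. That left 12617 in liver, 12686 in backfat and 13962 over both. Group means were fitted with limma's lmFit and eBayes, version 3.58.1 in R 4.3.3, and contrasts gave the sex effect (female minus male, averaged over feeding), the feeding effect (low minus high, averaged over sex), their interaction, and the tissue contrasts over all 16 arrays. Adjusted p-values are Benjamini-Hochberg values from limma over the probe sets of that test, with 0.05 as the threshold. The means ± SD of 4 arrays mix the 2 levels of the other factor. Where all arrays of 1 group lay below 4 and the other group's mean above it, the fold is given as "at least", from the brighter mean against 4. By a rule made after the values were seen, the report gives no difference for a named gene when a group had 1 or more arrays above 4 but no more than 2 of 4, or 4 of 8. The tests were first tested on simulated arrays with the real means and spreads. In the simulated sex comparison of liver, with 12617 probe sets, 66% of the probe sets changed by 1 on the log2 scale and 90% of those changed by 2 were recovered. In the simulated feeding comparison of backfat, with 12686 probe sets, 40% and 82% were. False calls numbered 4 and 6 in these 2 simulations. Each simulation used independent normal noise and changed 50 probe sets at each size, from 0.5 to 4. With fewer true changes the adjusted threshold is stricter, so recovery could be lower than these shares.

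A gene with several probe sets was represented by the one with the highest mean. There were 39 gene lists of pathways and cell type markers, and lists with at least 4 measured genes were tested with camera at a preset correlation of 0.01 and adjusted over lists. An estimated correlation, fry, the mean of all probe sets of a gene and an exact permutation test of list means per array were alternatives. For single probe sets the alternatives were no filter, a filter at 6, an intensity trend with robust estimation, quantile normalization, a shift to a common median, values under 4 set to 4, array weights, each array left out in turn, models with fewer terms, all 16 arrays in 1 fit and the animal as a block. The smallest exact two-sided p of 4 against 4 arrays is 0.0286. Lists, tests, named-gene rules and most alternatives were fixed before the data were examined.

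The text names, for sex and for feeding in a tissue, up to 10 higher and 10 lower genes of the largest difference past the threshold. Where fewer than 10 passed, the genes of lowest p made up 10, as values that did not pass. For the tissue contrast it names 10 in each direction, for an interaction up to 5 past the threshold or the 3 of lowest p, and for each list called by camera up to 4 members of lowest p. LEP, ADIPOQ, PPARG, LPL, FASN, SCD, CPT1A, PCK1, IGF1, CYP7A1 and EIF1AY are named where measured. List members past the threshold were added after their values were seen.

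Animal numbers in the labels pair the tissues of 4 males, 14 to 17. The correlation of their deviations from the group means between liver and backfat was 0.0874 for males 14 and 17 and 0.0549 for males 15 and 16. With 2 arrays per group these come in equal pairs. Female liver arrays carry the numbers 18 to 21 and female backfat arrays 20 to 23. Numbers 20 and 21 have opposite feeding levels in the 2 tissues, so females were not paired. The main fits over both tissues used no animal block, so the arrays of a male were treated there as separate animals. The random replicate block of the alternatives joined the arrays of each male across the tissues. In it every female array was a block of its own. The design text speaks of 8 animals. The labels do not say that arrays of a group came from separate litters or pens, so p-values measure the spread between these animals only.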

Results

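Gene expression was measured in liver and subcutaneous backfat of Iberian pigs, a fat Spanish breed, at 211 days of age. The animals were males and females kept on a high feeding level or on a level restricted by 20%, so that the study compared 2 tissues, 2 sexes and 2 feeding levels. Each of the 16 samples was hybridised to 1 Affymetrix porcine array, which gave 8 groups of 2 arrays. The labels do not say whether the males were castrated. The deposited values were GCRMA expression values on a log2 scale for 24123 probe sets. Array medians lay between 3.93 and 4.12, and 49.4% to 50.9% of the probe sets of an array stood above 4. Pearson's r across probe sets was 0.930 to 0.978 between liver arrays, 0.927 to 0.978 between backfat arrays and 0.584 to 0.645 across the tissues. EIF1AY, a gene named for the Y chromosome, stood between 8.69 and 9.47 on every array labelled male and between 2.78 and 2.97 on every array labelled female. The number of arrays limits the precision of every difference below.

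The first question was how the livers of females and males differed. Genes of steroid and drug metabolism were among those with the largest named differences. HSD17B2, an enzyme that oxidises estradiol and testosterone, stood at 10.49 ± 1.06 (SD, n = 4) in females and below 4 on all male arrays, which made it at least 89.9-fold higher in females when 4 is taken as the floor. CYP2A19, a cytochrome P450, was at least 75.1-fold higher in females by the same reckoning. In the other direction, CYP2C36 stood at 13.17 ± 0.37 (SD, n = 4) in males and 5.33 ± 1.81 (SD, n = 4) in females. In all, 572 of 12617 probe sets differed between the sexes (limma, Benjamini-Hochberg adjusted p below 0.05), 282 higher and 290 lower in females. They covered 229 of the 4928 genes with a symbol, and 289 of the called probe sets had no symbol.

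**Figure D1:**
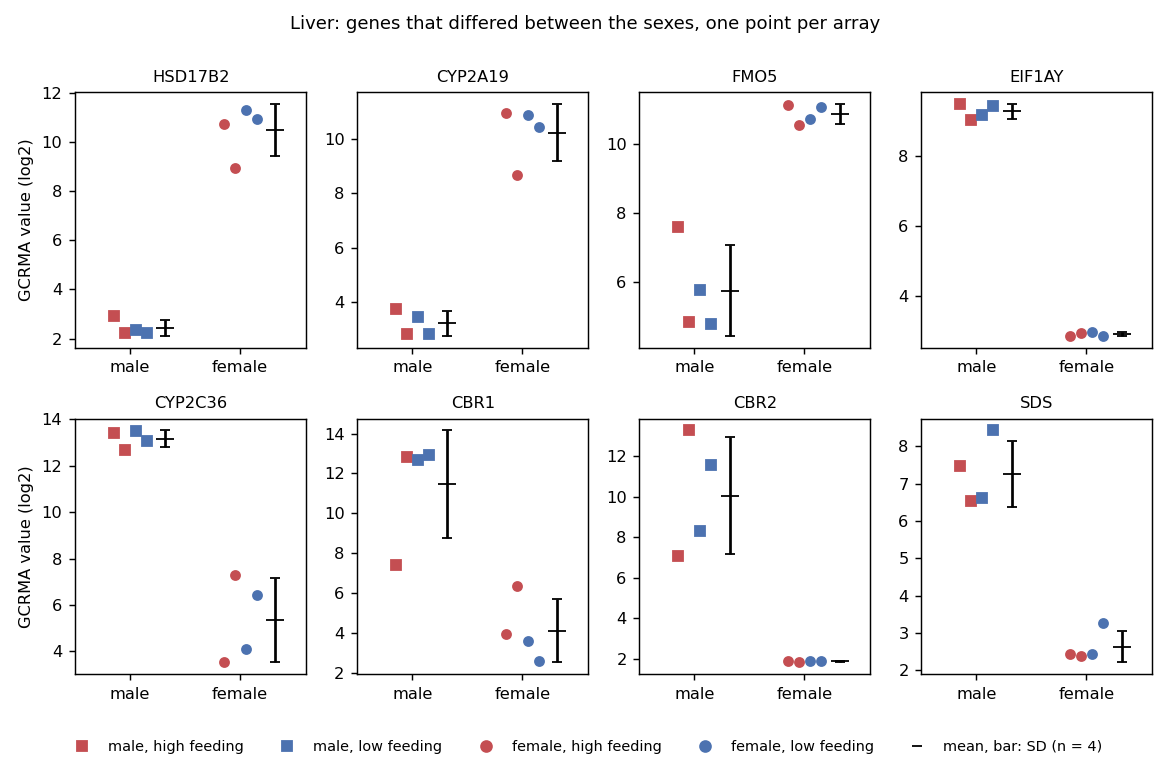
GCRMA values (log2, vertical axes) of 8 genes in the 8 liver arrays, by sex. Each point is an array, squares are males and circles females, red is the high and blue the low feeding level, and the black mark and bar are the mean and SD (n = 4). HSD17B2, CYP2A19 and FMO5 were higher on all female arrays, and the 5 other genes on all male arrays; CBR1 ranged widely among males, with 1 array at 7.40.

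The genes with the largest higher levels in females also held FMO5, a flavin-containing monooxygenase, with a female minus male log2 difference of 5.14 ± 0.59 (SE). CA3, a carbonic anhydrase, averaged 9.18 in females and was above 4 on 1 of 4 male arrays, and the mitochondrial carrier SLC25A48 averaged 7.68 and was above 4 on 2 of 4, so no difference is given for them. SULT1A3, a sulfotransferase, differed by 4.20. ACAA2, an enzyme of fatty acid oxidation, differed by 3.28. PDE6C, MIOX and OVGP1 were below 4 on all male arrays and at least 5.93-fold, 5.22-fold and 3.21-fold higher in females. The bound of MIOX was 3.38-fold without female 19 and 7.96-fold without female 21. Adjusted p-values of these genes ran from 7.52e-05 for PDE6C to 0.0309 for ACAA2. Among genes lower in females, the carbonyl reductases CBR2 and CBR1 had adjusted p-values of 0.0239 and 0.0208. CBR1 averaged 11.46 in males and was above 4 on 1 of 4 female arrays, so no difference is given. CBR2, EIF1AY, SDS, a serine-degrading enzyme, and SLC25A33 were below 4 on all female arrays and at least 66.4-fold, 38.7-fold, 9.60-fold and 5.08-fold lower in females. CBR2 ran from 7.07 to 13.27 among males, and its bound was 31.6-fold without male 17 and 132-fold without male 14. PLEK2 averaged 7.27 in males and was above 4 on 2 of 4 female arrays. The P450 enzyme CYP2B22 had a difference of -3.98, the glutamate transporter SLC1A2 -3.12 and GTF2F2 -2.87. CBR2 lost its call in 8 of 19 alternatives, CBR1, ACAA2 and PLEK2 in 7, SLC1A2 in 5, CYP2B22 in 3 and SULT1A3 and OVGP1 in 1. The second probe sets of HSD17B2, CA3 and GTF2F2 were called in the same direction, and those of CYP2C36 and SLC25A33 were too dim to be tested.

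Gene lists fixed before the data were examined were described next, with members past the threshold named after their values were seen. Of 11 measured genes of steroid hormone metabolism, 3 were higher and 1 lower in females, and 5 and 2 were when adjusted over the list alone. Beside HSD17B2 the higher ones were AKR1C1, with 2.68 ± 0.39 (SE), and HSD3B1, with 2.37 ± 0.32 (SE). The lower one was the estrogen sulfotransferase SULT1E1, with -1.81 ± 0.14 (SE). Of 22 drug metabolism genes, 3 were higher, CYP2A19, FMO5 and CYP2E1, and 3 lower, CYP2B22, FMO1 and CYP3A46. Adjusted over the list alone, 3 were higher and 4 lower. CYP2E1 differed by 2.39 and FMO1 by -1.27. Of 14 genes of the urea cycle and amino acid breakdown, ASL was higher, with 1.16, and SDS, BCKDHA and HPD were lower; BCKDHA, a subunit of the branched-chain keto acid dehydrogenase, had -2.20 ± 0.13 (SE). Adjusted over the list alone, 1 was higher and 4 lower. The triglyceride synthesis genes DGAT1 and GPAM were higher, with 1.54 and 1.24, and the other 6 measured did not pass. Adjusted over that list alone, 3 were higher and 1 lower. In fatty acid oxidation, ACAA2 and PDK4 were higher and ACADL lower among 19 genes, with differences of 3.28, 1.75 and -1.28. Adjusted over that list alone, 2 were higher and 2 lower. The call was lost in 9 of 19 alternatives for GPAM, whose low-fed females lay within the range of the males, in 7 for ASL, PDK4, FMO1 and CYP3A46, in 5 for HSD3B1, in 4 for AKR1C1 and HPD and in 2 for CYP2E1.

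Single members of other lists also passed. INSIG1 and GPT were higher in females, by 1.02 and 0.93. ABCA1, the acute-phase gene APCS and the lipid droplet gene PLIN3 were lower, with -0.80, -1.58 and -1.76. The call was lost in 9 of 19 alternatives for ABCA1 and PLIN3, 9 of 18 for GPT and 7 of 19 for INSIG1. Camera, which sets the genes of a list against all other genes, called 1 of 31 lists. The heat shock list stood lower in females, with a median difference of -0.73 and an adjusted p = 0.0161. That call was lost with an estimated correlation between genes (adjusted p = 0.953). Of its 14 genes, CRYAB and DNAJB1 were lower, with -2.32 and -1.13, and the other 12 did not pass. Of 19 alternatives, 4 lost the call of CRYAB and 7 that of DNAJB1. Adjusted over the list alone, 4 were lower and 1 was higher. HSP90AA1 had -0.72 (adjusted p = 0.0525), with 2 of its 4 other probe sets of opposite sign, and HSPB8 had 0.84 (adjusted p = 0.0525). Genes named whatever their result did not pass, with adjusted p-values between 0.113 and 0.931 for IGF1, CPT1A, FASN, PCK1, SCD and CYP7A1. IGF1 had -1.01 ± 0.29 (SE), CPT1A -0.46, PCK1 0.92, SCD 1.0 and CYP7A1 1.6 ± 1.17 (SE). FASN had -0.23, and its other tested probe set had the opposite sign. The heat shock call was lost without male 15, female 20 or female 21. The count of 572 fell to 177 without male 16, 188 without male 15, 189 without female 19, 221 without female 20, 257 without female 18, 313 without male 17 and 369 without female 21. It was 333 with no filter on dim probe sets and 907 when all 16 arrays shared 1 fit (910 with the animal as a replicate block).

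In backfat, the same question gave 14 of 12686 probe sets, 7 higher and 7 lower in females. Of these, 2 had a symbol. EIF1AY was below 4 on all female arrays and at least 27.6-fold lower in females (adjusted p = 1.20e-06). LOC396706 was also lower (adjusted p = 0.00776). It was below 4 on all female arrays and averaged 3.80 in males, so no fold is given, and its call was lost in 7 of 17 alternatives. Among the unnamed probe sets, the 2 with the largest fitted differences towards females averaged 10.64 and 10.91 in females and lay below 4 on all male arrays, and the 2 towards males averaged 11.22 and 10.91 in males and lay below 4 on all female arrays.

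Of the 14 probe sets called in backfat, 11 were also called in liver, all 11 in the same direction. Only 1 was tested in liver and not called, and the rest did not enter the liver test. Independent lists among the 11399 probe sets tested in both tissues would share 0.474. The next genes by p did not pass. ANPEP, a membrane peptidase, had -2.02 ± 0.24 (SE; adjusted p = 0.0687), and PTN -1.01. COL3A1 averaged 4.59 in males and was above 4 on 2 of 4 female arrays. CIRBP had 1.02. METRNL and TRIP10 were below 4 on all male arrays and at least 1.48-fold and 1.34-fold higher in females. PCLAF was above 4 on the 2 arrays of high-fed females alone, at 6.61 and 5.78. The X-linked gene KDM6A had 0.98 ± 0.15 (SE; adjusted p = 0.232). The fat cell hormones ADIPOQ and LEP had 0.77 ± 0.37 (SE) and 0.41 ± 0.40 (SE), LPL 0.37, PPARG 0.09 and PCK1 0.11. SCD had -0.04, FASN -0.13, IGF1 -0.10 and CPT1A -0.16, all with adjusted p-values of 0.822 or more.

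**Figure D2:**
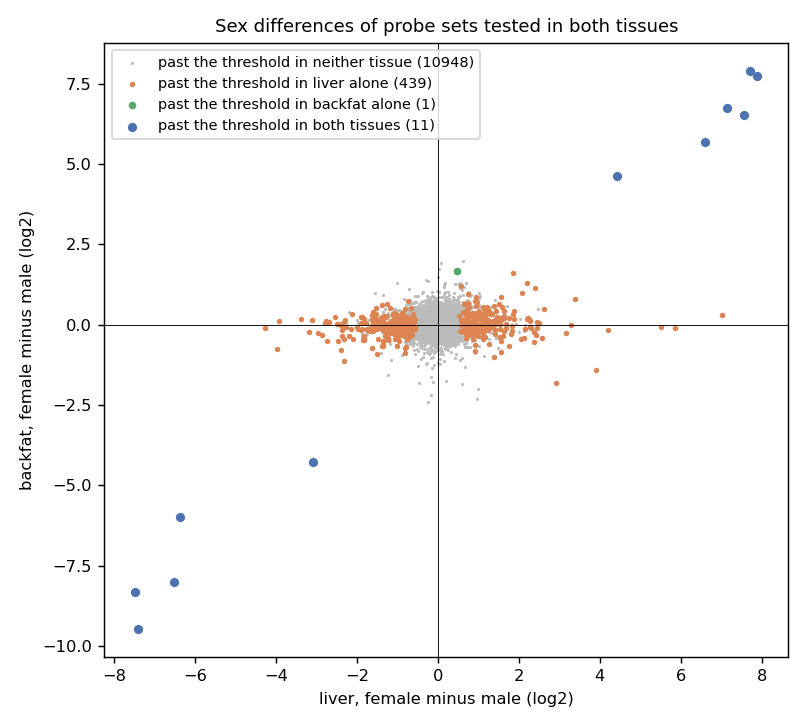
Female minus male differences (log2) of probe sets tested in both tissues, with liver on the horizontal and backfat on the vertical axis. Each point is a probe set, coloured by where its adjusted p was below 0.05; the 11 called in both tissues lie far from 0 on both axes, and the 439 called in liver alone spread along the horizontal axis.

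Camera called 3 of 28 lists for sex in backfat, and each lost its call with an estimated correlation (adjusted p = 0.914). No member of them passed over all probe sets. Cholesterol synthesis and uptake stood higher in females, with a median of 0.11 over 11 genes (adjusted p = 0.0295). Adjusted over the list alone, 1 was higher. Its lowest p-values were those of HMGCS1, with 0.58, INSIG1, with 0.44, MSMO1, with 0.43, and NSDHL, with 0.32. Lipoprotein secretion stood lower, with a median of -0.37 over 8 genes (adjusted p = 0.0375), and 2 were lower adjusted over the list alone. ABCA1 had -0.72, SCARB1 -0.52, APOA1 -0.47 and APOE -0.14. The list of X-linked genes stood higher, with a median of 0.39 over 4 genes (adjusted p = 0.0375), and 2 were higher and 1 lower adjusted over the list alone. KDM6A, USP9X and EIF1AX had 0.98, 0.43 and 0.36, and ZFX was below 4 on all female arrays and at least 1.17-fold lower; the other probe set of USP9X had the opposite sign. With all 16 arrays in 1 fit, 27 probe sets were called in place of 14 (26 with the animal as a replicate block). The number of lists called was 0 without male 15 or female 22, 1 without female 20, and 5 without male 16 or male 17. Cholesterol synthesis and uptake lost its call without male 15, female 20 or female 22. Lipoprotein secretion kept it in 3 of 8 such runs, without male 14, 16 or 17, and the X-linked list in 3, without male 16, male 17 or female 23.

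Feeding level was the study's treatment, and its effect on liver was taken as low minus high. The lowest p-value of a named gene was that of CRP, the acute-phase protein, which stood at 9.16 ± 0.78 (SD, n = 4) at the low and 12.57 ± 0.72 (SD, n = 4) at the high level, without overlap. Its log2 difference was -3.40 ± 0.39 (SE), with an adjusted p = 0.266. No probe set passed the threshold among 12617 in limma, and 1455, or 11.5%, had an unadjusted p below 0.05 (870 without male 15). LBP, which binds bacterial lipopolysaccharide, had -1.80 ± 0.29 (SE), and DIO1, a thyroid hormone deiodinase, -2.14 ± 0.30 (SE). DIO1 overlapped between the levels, with low arrays from 4.75 to 8.81 and high arrays from 8.79 to 9.11. Its SE rests on the spread within groups of the same sex and feeding level, and leaves out any difference between the sexes. GSN had 1.45 ± 0.19 (SE). ALG14 and NUDT22 were below 4 on all low arrays and at least 1.51-fold and 1.42-fold lower there. VKORC1 had -1.02, POLB -0.92, ANXA1 -0.91 and NT5DC1 -0.79. All these genes shared an adjusted p of 0.266. CRP, LBP, DIO1, GSN and POLB passed in 2 of 19 alternatives and ALG14 in 2 of 18, and VKORC1, ANXA1, NT5DC1 and NUDT22 in none. CYP7A1, the rate-limiting enzyme of bile acid synthesis, averaged 7.95 at the high level and was above 4 on 2 of 4 low arrays (adjusted p = 0.365). The fatty acid synthesis genes SCD and FASN had -1.29 ± 0.99 (SE) and -1.16 ± 0.91 (SE). CPT1A had 0.67, PCK1 0.45 and IGF1 -0.54.

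**Figure D3:**
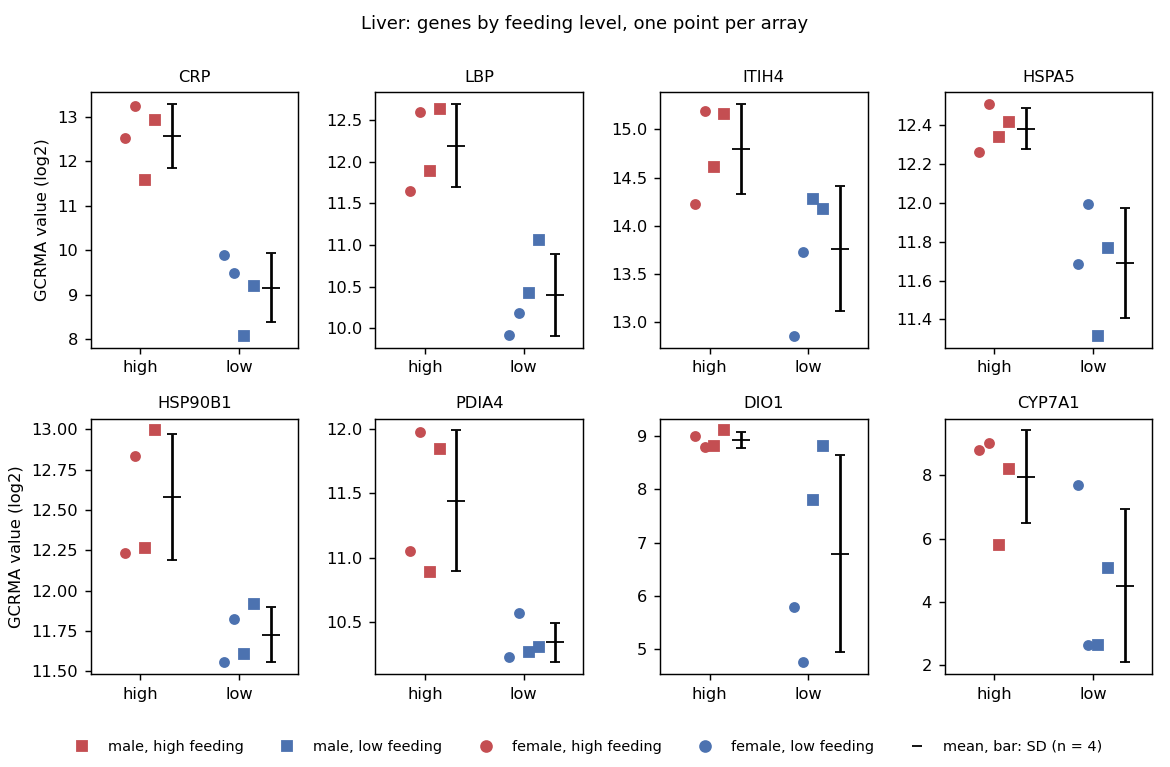
GCRMA values (log2, vertical axes) of 8 genes in the 8 liver arrays, by feeding level. Each point is an array, squares are males and circles females, and the black mark and bar are the mean and SD (n = 4). CRP, LBP, HSPA5, HSP90B1 and PDIA4 did not overlap between the levels, and none of the 8 genes passed the adjusted threshold. All but CYP7A1 were named for a low p on these same arrays. Nor did 745 of the 12617 probe sets overlap, or 5.90% where chance gives 2.86% (a tally added after the values were seen).

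Camera called 7 of 31 lists for feeding in liver, and all 7 lost the call with an estimated correlation (adjusted p = 0.826). No member of these lists passed over all probe sets. The unfolded protein response list stood lower at the low level, with a median of -0.69 over 13 genes (adjusted p = 0.00600), and 6 were lower adjusted over the list alone. The chaperones HSPA5 and HSP90B1 had -0.69 and -0.85, DNAJC3 -1.25 and PDIA4 -1.10. The acute-phase list had a median of -0.21 over 14 genes (adjusted p = 0.0269), with 3 lower adjusted over the list alone. Its lowest p-values were those of CRP, LBP, ITIH4, with -1.03, and APCS, with -0.54. Oxidative phosphorylation had a median of -0.14 over 23 genes (adjusted p = 0.0391), none of them past the list's own adjustment. SDHC had -0.34, SDHD -0.30, NDUFB3 -0.28 and ATP5B -0.26.

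Extracellular matrix genes stood higher at the low level, with a median of 0.20 over 15 genes (adjusted p = 0.00600). With an estimated correlation this call and the others of this paragraph were lost (adjusted p = 0.826). The list's mean was 7.43 on the high-level array of female 20, against 6.90 to 6.98 on the other high arrays. DCN had 0.86, BGN 0.47, FBN1 0.30 and COL3A1 0.24. The circadian clock list had a median of 0.38 over 6 genes (adjusted p = 0.0269), and 1 was higher adjusted over the list alone. PER1 had 0.71, CRY2 0.64, DBP 0.56 and NFIL3 0.21. Fatty acid oxidation had a median of 0.12 over 19 genes and gluconeogenesis one of 0.36 over 8 genes (both adjusted p = 0.0269). CPT1A, ACADVL, ACAA1 and ANGPTL4 had 0.67, 0.44, 0.40 and 0.36, and PCK2, SLC37A4, PC and GPT had 0.45, 0.45, 0.37 and 0.36. In the extracellular matrix, fatty acid oxidation and gluconeogenesis lists none passed the list's own adjustment. With all 16 arrays in 1 fit, 11 probe sets were called for feeding in liver, with or without the animal as a replicate block, and 1 was called without male 17. In place of 7 lists, 1 was called without female 20, 2 without female 21 and 4 without male 16 or male 17. Oxidative phosphorylation kept its call in 2 of 8 such runs, without male 14 or female 18. Acute phase and fatty acid oxidation lost theirs without male 16, male 17, female 20 or female 21, and gluconeogenesis without male 15, male 17, female 20 or female 21. The unfolded protein response lost its call without female 20 or 21, the circadian clock without male 16, female 18 or female 20 and the extracellular matrix without female 19.

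In backfat, the feeding levels were compared in the same way. LEP, which encodes the fat cell hormone leptin, stood at 7.46 ± 0.41 (SD, n = 4) at the low and 9.52 ± 1.05 (SD, n = 4) at the high level, a difference of -2.06 ± 0.40 (SE; adjusted p = 0.203). PCK1, which serves gluconeogenesis and glyceroneogenesis, stood at 8.54 ± 0.58 (SD, n = 4) and 5.79 ± 1.31 (SD, n = 4), a difference of 2.75 ± 0.66 (SE; adjusted p = 0.252). Of 10 genes named whatever their result, these 2 did not overlap between the levels. Nor did 838 of the 12686 probe sets, or 6.61% where chance gives 2.86% (a tally added after the values were seen). No probe set passed in limma, 1410, or 11.1%, had an unadjusted p below 0.05, and the smallest adjusted p was 0.0594. The 1410 became 2364 without female 22 and 753 with the mean of the hepatocyte markers as a covariate, which was also added later. Those markers are not specific to hepatocytes in backfat, as described below. The lowest p-values of named genes were those of UBD, with -1.58 ± 0.17 (SE), and FLVCR2, with 1.06 ± 0.11 (SE), both at an adjusted p = 0.10. EHD4 had -1.64. GP91-PHOX, a subunit of the phagocyte oxidase, averaged 5.71 at the high level and was above 4 on 2 of 4 low arrays. CPM was below 4 on all low arrays and at least 2.65-fold lower there. PCLAF was below 4 on all arrays but those of the 2 high-fed females, which alone carry its difference. GRB10 had 0.90 and FBP1 0.88, and HS3ST3A1, below 4 on all high arrays, was at least 1.25-fold higher at the low level. ADIPOQ had -0.28, LPL -0.16, SCD -0.12, PPARG -0.11, FASN -0.01, IGF1 0.04 and CPT1A 0.42. The sign for FASN turned with quantile normalization. LEP, FLVCR2, EHD4 and GRB10 passed in 2 of 20 alternatives and UBD in 1 of 20. CPM and GP91-PHOX passed in 2 of 19 and PCLAF in 2 of 17, and PCK1, FBP1 and HS3ST3A1 in none.

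**Figure D4:**
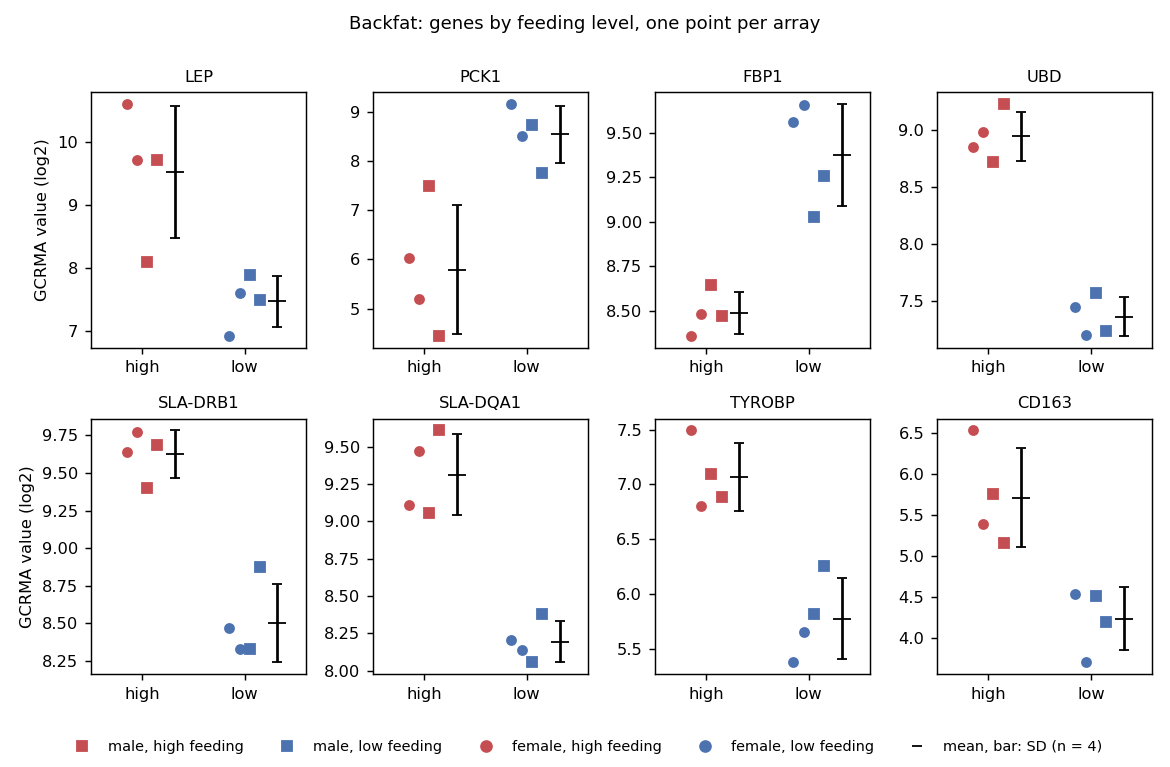
GCRMA values (log2, vertical axes) of 8 genes in the 8 backfat arrays, by feeding level. Each point is an array, squares are males and circles females, and the black mark and bar are the mean and SD (n = 4); none of the 8 genes passed the adjusted threshold.

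Camera called 7 of 28 lists for feeding in backfat. All lost the call with an estimated correlation, where adjusted p-values ran from 0.499 to 0.689, and no member passed over all probe sets. Macrophage markers stood lower at the low level in all 11 genes, with a median of -1.23 (adjusted p = 1.73e-08; adjusted p = 0.499 with an estimated correlation), and 8 were lower adjusted over the list alone. FCER1G, CD163, AIF1 and TYROBP had -1.75, -1.48, -1.35 and -1.29. All 8 class II antigen presentation genes were negative, with a median of -1.01 (adjusted p = 1.73e-08; adjusted p = 0.499 with an estimated correlation), and 7 were lower adjusted over the list alone. SLA-DRB1, SLA-DQA1 and SLA-DQB1 had -1.12, -1.12 and -0.93. SLA-DOA averaged 1.99 at the low and 3.49 at the high level, both below 4, so no difference is given. In 2 of 20 alternatives FCER1G, AIF1, TYROBP and SLA-DRB1 passed over all probe sets, and in 2 of 17 SLA-DOA did. CD163, SLA-DQA1 and SLA-DQB1 passed in none. The interferon response list had a median of -0.35 over 17 genes (adjusted p = 0.0198), with 2 lower adjusted over the list alone. IRF1 had -1.63, ISG15 -0.96, GBP2 -0.93 and IFIT2 -0.50. The proliferation list had a median of -0.57 over 4 genes (adjusted p = 0.0499), with 3 lower adjusted over the list alone. PCNA, STMN1 and RRM1 had -0.60, -0.54 and 0.16, and TOP2A was below 4 on all low arrays, with a bound of 1.11-fold that fell to 0.914, and so was lost, without female 21. The interferon call was lost without male 14 or 15, and the proliferation call held in 3 of 8 runs that left out 1 array, without male 16, male 17 or female 21. Beside these lists, the array of female 21 at the high level had weaker hybridization controls than the other backfat arrays, with a mean of 8.80 against 9.71 to 9.98.

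Hepatocyte markers stood higher in backfat at the low level, with a median of 1.04 over 9 genes (adjusted p = 0.0196; adjusted p = 0.689 with an estimated correlation). None passed the list's own adjustment. ALB and RBP4 had 2.37 ± 1.23 (SE) and 0.40. The list is not specific to hepatocytes in backfat. RBP4, which is also on the fat cell list, stood between 8.45 and 9.87 on all backfat arrays. APOA1, another member, stood between 10.68 and 11.68. CYP2E1 and SERPINA1 were below 4 on all high arrays. SERPINA1 was above 4 on 2 of 4 low arrays, so no fold is given. The mean of CYP2E1 was at least 1.89-fold higher at the low level when 4 is taken as the floor (limma, adjusted p = 0.430). The levels overlapped, since CYP2E1 stood at 2.20 on the low array of male 16 and at 2.62 to 3.24 on the high arrays. The bound of CYP2E1 was 3.54-fold without male 16 and 1.04-fold without female 20. Gluconeogenesis had a median of 0.21 over 7 genes (adjusted p = 0.0198; adjusted p = 0.499 with an estimated correlation), with 3 higher adjusted over the list alone, and PCK1, FBP1, GPT and PCK2 had 2.75, 0.88, 0.81 and 0.21. Fatty acid oxidation had a median of 0.18 over 18 genes (adjusted p = 0.0201; adjusted p = 0.689 with an estimated correlation), with none past the list's own adjustment. PDK4 had 1.22, ANGPTL4 0.94, HADHA 0.54 and ACADS 0.26. With all 16 arrays in 1 fit, 53 probe sets were called for feeding in backfat (54 with the animal as a replicate block), and 1 was called without male 16, female 22 or female 23. Without female 22, 4 lists were called in place of 7, and the hepatocyte marker call was lost without male 15, female 20 or female 21. That of gluconeogenesis was lost without female 22 and that of fatty acid oxidation without male 16, female 20 or female 22.

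Whether feeding acted differently in the sexes was tested as an interaction. No probe set passed in either tissue in limma. Chance gives an unadjusted p below 0.05 to a share of 0.05. In liver 685 probe sets had one, or 5.43%, and in backfat 668, or 5.27%. These counts moved with single arrays: in liver to 1082 without female 18 and 456 without female 20, and in backfat to 1637 without female 22 and 367 without female 23. The lowest p-values in liver were those of UBL7, GATAD2A and C5H12orf10 (adjusted p = 0.751), with interactions of 1.86, 1.58 and 1.61. In backfat they were those of CAPG, PCLAF and S100A4 (adjusted p = 0.893), with -2.22 for CAPG and -3.59 for S100A4; PCLAF was above 4 in high-fed females alone, so no value is given. Without male 17, 1 probe set passed in liver. In simulated data, this test in liver recovered 40% of probe sets changed by 2 on the log2 scale.

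Backfat and liver differed in 10572 of 13962 probe sets, 6082 higher in backfat and 4490 higher in liver. FABP4, the fat cell fatty acid binding protein, stood at 14.79 ± 0.14 (SD, n = 8) in backfat and 3.64 ± 0.56 (SD, n = 8) in liver. LPL was at least 592-fold, ADIPOQ at least 359-fold and the hormone-sensitive lipase LIPE at least 87.9-fold higher in backfat, each below 4 on all liver arrays. F2RL2, APOD and COL15A1 were at least 231-fold, 190-fold and 182-fold higher. ALDOC, SLPI and OXCT1 averaged 12.15, 12.19 and 12.15 in backfat and were above 4 on 4, 3 and 4 of the 8 liver arrays. SPP2 was below 4 on all backfat arrays and at least 646-fold higher in liver. SERPINA3-2, the transport protein TTR, LOC396685, APOA2, plasminogen (PLG), APOH, SERPINA1, HPX and APOC2 averaged 13.61 to 14.27 in liver. They were above 4 on 1 or 2 of the 8 backfat arrays, with averages below 4, so neither a size nor an order is given. Adjusted p-values of these 20 genes lay between 4.06e-15 and 1.04e-09. The median difference over all tested probe sets was 0.15, and 0.03 after the arrays were shifted to a common median, which gave 5436 higher in backfat and 5123 higher in liver.

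The difference between females and males was not the same in the 2 tissues for 308 probe sets, 156 with a higher and 152 with a lower female minus male difference in backfat than in liver. Of these, 261 were also called for sex in liver and 7 for sex in backfat. HSD17B2, at least 89.9-fold higher in females in liver, averaged 2.19 and 2.20 in female and male backfat, below 4 (interaction adjusted p = 7.24e-06). MIOX and GPR1 were called in the same direction, with averages below 4 in backfat and on all male liver arrays. KCTD9 had an interaction of 2.82, with a liver difference of -2.79, and MKS1 was called in that direction, below 4 on all female liver arrays. The count was 174 without the backfat array of male 16, 195 without that of male 15 and 197 without that of female 23.

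The effect of feeding differed between the tissues in 3 probe sets, all without a symbol. One averaged 6.30 at the low and 4.82 at the high level in backfat and 4.84 and 4.78 in liver. The others averaged 5.52 and 5.0 at the low level in backfat, with means below 4 at its high level and in liver. In all, 1225 probe sets, or 8.77%, had an unadjusted p below 0.05. CRP, DUOX2 and FKBP10 had the lowest p-values of named genes and did not pass, with adjusted p-values of 0.116, 0.116 and 0.119. CRP averaged below 4 at both levels in backfat, and DUOX2 and FKBP10 in liver, so no size is given. The count was 34 without the backfat array of female 22, 17 and 14 without the liver and backfat arrays of male 14, 12 without the liver array of male 17 and 5 without the backfat array of female 21. It was 1 without the liver array of any of males 15 and 16 and females 18, 19, 20 and 21, or the backfat array of male 15 or 16. Among the 8 male arrays with the animal as a replicate block, no probe set passed, and 1 did without the block.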

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

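The tests of explanations for the hepatocyte transcripts, for the class II and macrophage genes and for the backfat array of female 21, and the exact permutation tests of list means, were chosen only after the values they measure had been seen. The camera tests of these lists and the counts over other splits of the arrays were planned. Of 115 groups of 4 or 8 arrays examined for an array far from the others, 9 held one, and chance gives about 1 in 20.

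In liver, the array of male 17 had the lowest mean correlation with the other liver arrays, 0.949. The same array stood apart from the other males in DNAJB1, at 7.49 against 8.02 to 8.13. In APCS it stood at 13.96 against 13.79 to 13.81, a small gap beside tightly packed values. SLC1A2 stood at 6.36 on the array of female 21, far below the other females, and CBR1 at 7.40 on that of male 14, far below the other males. The mean of the extracellular matrix list was 7.43 on the liver array of female 20, apart from the other arrays at the high level. In backfat, the mean of the class II list was 8.43 on the array of male 14, apart from the other arrays at the high level.

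The sex difference differed between the tissues by the interaction test in 308 probe sets, among them KCTD9 with 2.82, MKS1 with 2.05, GPR1 with -2.69, MIOX with -3.80 and HSD17B2 with -8.07. All but that of KCTD9 rest on liver values below 4 in 1 sex, so they are fitted values and give no size. The feeding difference differed between the tissues in 3 probe sets.

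Calls were also counted over other splits of the same arrays. For sex in liver, 1 of 35 splits gave as many calls, the real one with 606 in a test of 4 against 4 arrays, and the highest other gave 2. For sex in backfat it was also 1 of 35, with 12 and 2, so chance can be excluded for both. For feeding in liver the real count was 0, which all 35 of 35 splits reach whatever the data, so this tally decides nothing; the highest, 606, was the split by sex. For feeding in backfat, 2 of 35 splits gave as many as the real 2, so chance cannot be excluded at that share, though the other was the split by sex with 12, itself a real difference. For backfat against liver, 1 of 100 drawn splits gave as many, the real 10343 against 7726. For the tissue by sex interaction, 4 of 100 did, the real 276 against 339 in the highest other. Each draw regrouped the arrays of the 2 tissues separately, which breaks up the sex difference within each tissue too. The tally therefore cannot show whether that difference was equal in the tissues, and decides nothing about the interaction. For the tissue by feeding interaction, with draws of the same kind, 11 of 100 gave as many, the real 4 against 291, so chance cannot be excluded. Such draws can divide a tissue by sex, but the arrays of the draw that gave 291 were not recorded, so its cause was not tested.

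The array of female 21 in backfat had a mean correlation with the other backfat arrays of 0.944, the lowest. Its bioB, bioC and bioD hybridization controls averaged 8.80, against 9.71 to 9.98 on the 7 other backfat arrays. Degraded RNA would raise the difference between probe sets at the 3' and 5' ends of the actin, GAPDH and elongation factor control genes. That difference was above the other arrays in 0 of the 3 genes and below all of them in each, with 2.19 against 2.85 to 3.41 for actin. This argues against degraded RNA. Weaker hybridization or staining remains a candidate explanation. The control value of 8.80 is one of the values by which the array was flagged, so it is no separate test of it. No biological explanation was tested.

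Hepatocyte transcripts differed between backfat arrays. Over 100 liver-restricted probe sets the median Pearson r with ALB across the 8 backfat arrays was 0.544 (one-sided exact permutation p = 0.00241; 0.544 without the 2 arrays farthest from the median of ALB) and the median Spearman rho was lower, 0.440 (one-sided exact permutation p = 0.0279). Liver RNA carried over may give this, with 55 of the 100 above an r of 0.5. On the 4 arrays with ALB above 8, other abundant liver transcripts lay further below their liver level than ALB did, by medians of -2.84 to -4.42, which goes against carry-over in liver proportions. It does not settle the question, because ALB lies at percentile 99.971 of the liver probe sets, where a compressed scale would understate its own gap. Feeding level stays open too, with an exact two-sided permutation p of 0.143 for the mean of the hepatocyte markers. Its low minus high difference was 1.24, between 0.87 and 1.70 without single arrays. That mean includes RBP4 and APOA1, which were above 4 on all backfat arrays.

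Class II and macrophage genes stood lower at the low feeding level in backfat, with a median of -1.12 over 19 genes. Female 21 alone is argued against, since the median without that array was -0.99. An equally large fall of all cells other than fat cells is argued against as well: endothelial and extracellular matrix genes had a median of -0.051 over 25 genes (95% bootstrap interval over genes -0.226 to 0.0805). The matrix genes alone had 0.02 over 18, while 6 of 7 endothelial genes were negative, with a median of -0.30 (camera, adjusted p = 0.105), so a smaller fall of endothelial cells stays open. Macrophage markers outside class II had a median of -1.23, so fewer macrophages may account for it, as a hypothesis found and tested on the same arrays. Feeding level, the difference the design names, stays among the open explanations. The exact two-sided permutation p was 0.0286 for the mean of each list, the smallest that 4 against 4 arrays can give, and 0.160 after adjustment over the lists.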

How the results depend on the processing

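The exact permutation test of list means and the hepatocyte covariate were chosen after seeing the data. The markers behind that covariate are not specific to hepatocytes in backfat. The fixed replicate block could not run for the tissue by sex interaction, since it holds males alone. Named genes were counted once in each comparison they were named in. Of 67 past the threshold, 43 passed in every alternative run, none of the 67 reversed, and of 132 not past it, 29 passed in some. The 43 held every named gene of backfat against liver and of the tissue by sex interaction. Those that lost a call were all named for sex in liver, except LOC396706 in backfat. Of 234 values of called lists, 121 stayed past the threshold and 113 did not. Among the 113 are all values of the exact permutation test, which could hardly pass. For the changes below the cause was not tested, except that leaving out arrays or filters changes the number of arrays or probe sets by construction. Signal over background limits every difference near the floor.

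With no filter, the count for sex in liver was 333 and for tissue by feeding 15. The stricter filter and the trend with robust estimation each left 1 for tissue by feeding. All 16 arrays in 1 fit gave 907 for sex in liver, 11 for feeding in liver, 27 for sex in backfat and 53 for feeding in backfat. With the animal as a random replicate block these were 910, 11, 26 and 54. Feeding in backfat gave 2 with the factor alone and 1 in the additive model. Among the 8 males, the replicate block gave 8671 probe sets for tissue and 8958 did without it, and for tissue by feeding 0 and 1. The random replicate block gave 10588 for tissue, 321 for tissue by sex and 3 for tissue by feeding.

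Lists called for sex in liver, feeding in liver, sex in backfat and feeding in backfat numbered 0, 0, 0 and 3 with fry. They numbered 0 in each with an estimated correlation and with the exact permutation test. For the exact test this count shows little, since its smallest p is 0.0286. After adjustment that p falls below 0.05 only if most of the lists reach it. With no filter, 4 were called for feeding in liver and 1 for sex in backfat.

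Leaving out 1 array at a time gave 177 to 449 for sex in liver, 0 to 1 for feeding in liver and for its interaction with sex, 11 to 15 for sex in backfat, 0 to 1 for feeding in backfat, 10176 to 10580 for tissue, 174 to 386 for tissue by sex and 1 to 34 for tissue by feeding. Lists numbered 0 to 3, 1 to 10, 0 to 5 and 4 to 9 in the order above. Class II and macrophage lists kept their calls in 8 of 8 at the preset correlation, with adjusted p at most 0.000149 and 8.05e-06, but both lost them at the estimated correlation (adjusted p = 0.499).

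Signs turned in genes that did not pass. Leaving out arrays, sex in liver ranged from -0.034 to 2.04 for SCD and -1.07 to 0.61 for FASN; feeding in liver from -0.15 to 1.05 for PCK1 and -0.086 to 0.14 for EIF1AY. Sex in backfat ranged from -0.65 to 0.88 for PCK1, -0.029 to 0.20 for PPARG, -0.14 to 0.054 for SCD, -0.27 to 0.063 for IGF1, -0.28 to 0.028 for FASN and -0.44 to 0.13 for CPT1A. Feeding in backfat ranged from -0.12 to 0.21 for IGF1, -0.16 to 0.15 for FASN, -0.229 to 0.00109 for PPARG and -0.66 to 0.094 for ADIPOQ. FASN was 0.018 with quantile normalization. With the hepatocyte covariate PCK2 was -0.060, IGF1 -0.18 and PPARG 0.071.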

Other observations

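The design text speaks of 8 animals, while the female numbers run from 18 to 21 in liver and 20 to 23 in backfat, and numbers 20 and 21 carry opposite feeding levels in the tissues. A shift of 2 between the number series was tested on 326 probe sets whose deviations went together in the 4 males. That pairing ranked 1 of 24, with a mean correlation of 0.503 against 0.407 for the next, as a shifted numbering may give. Only 4 of the 24 pairings keep the feeding level, and deviations within groups of 2 mirror each other, so the rank is weak evidence and females stayed unpaired.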
